A study of Homo sapiens with 8 samples.

How the data were processed

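RNA was measured in 8 libraries of HaCaT cells, an immortalised human keratinocyte line, in which CARD14 had been knocked out. Per the labels' protocols, cells in 10 cm dishes were transfected with 9 ug of a plasmid that encodes CARD14 followed by a self-cleaving peptide and eGFP, the medium was changed after 2 h, and GFP-positive cells were sorted 24 h after transfection. The plasmid carried wild-type (WT) CARD14 or the variant R820W, N737H or I593T. RNA was extracted with a mirVana kit and libraries were made with a low-input kit from NEBNext, per the labels' protocols. Each of the 4 groups had 2 libraries, titled A and B. The series text speaks of 2 independent experiments, and the letters were read as those experiments, although the labels do not tie the letters to them in words.

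The authors deposited 1 table of whole-number read counts per gene symbol for the 8 libraries, with no normalization. The submitters' processing notes name the hg19 build and the tools FastQC, MACS2 and DESeq2, with no versions and no roles. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here. Reads shared by paralogs, read-through models or overlapping genes can therefore have been split in ways that cannot be checked. The table has 28518 gene rows, of which 5569 had no count in any library. Of the names, 27 look like dates, the form that spreadsheet programs give to some symbols, and 2 names occur more than once. Symbols that the table lacks were looked up through the synonyms of a RefSeq gene table of a later assembly, from which no coordinate was used. Only 1 of 13 mitochondrially encoded genes was found, so that list was not tested.

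Total counts ranged from 17892608 to 24629860 per library. Genes were kept by edgeR's filterByExpr with the 4 groups, which left 14834 genes holding 99.9% of the counts. Counts were normalised by the trimmed mean of M values and fitted with edgeR's quasi-likelihood model on all 8 libraries, with group means alone and 4 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The 7 comparisons were each variant with WT, the mean of the 3 variants with WT, and the 3 pairs of variants. Standard errors were derived from the fitted log2 fold change and its F statistic, and intervals are at 95%. CPM values were computed by edgeR's cpm function from the counts and the normalised library sizes. Values within a replicate letter are differences of log2 CPM with a prior count of 2.

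There were 28 gene lists fixed before the data were examined, of which 26 had at least 3 tested members. They were tested with limma's camera on voom values with a preset inter-gene correlation of 0.01, adjusted over 26 lists and 3 comparisons with WT together (78 tests). Camera with an estimated correlation and fry were run beside it. The genes named in the text were chosen by a rule also fixed before the data were examined. CARD14 and MYC are always named. For each variant against WT the rule takes 5 genes up and 5 down, past the threshold, with a mean of at least 5 CPM and the same direction in A and in B. Where too few genes pass, it fills with those of smallest p that meet the other conditions. The mean of variants and the pairs of variants take 3 up and 3 down. List members past the threshold are named, up to 2 per list, and a described list may name its 2 members with the highest mean level. Other genes named were chosen after their values were seen, and the text says so. Results that need items withheld for evaluation are not reported here.

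Libraries with the same letter were checked for shared deviations. The correlations of their deviations from the group means were 0.024 for WT with N737H and 0.31 to 0.41 for every other pair. The first principal component (33.3% of the variance) separated the 4 A libraries from the 4 B libraries. Pairing by letter rests on reading the letters as the 2 experiments, which the labels do not state, and a fit with the replicate letter as a block was run as an alternative. The main fit has no block, so its spread, and with it each SE, interval and p-value, holds the difference between the letters. The common biological coefficient of variation was 0.262 without the block and 0.190 with it. No pair of libraries agreed within sampling noise. The smallest chi-square per gene between any pair was 6.56, so all 8 libraries were counted as separate samples. With 2 libraries per group, p-values measure the spread between these libraries.

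Alternatives were another normalization (RLE), no filter on low counts, a filter of at least 10 counts in at least 6 libraries, DESeq2, limma voom, the replicate block in edgeR and in DESeq2, the removal of CARD14 and the mitochondrial gene before normalization, a fit of only the groups compared, and each library left out in turn. DESeq2 was given the 22949 genes with a count and used its own filter, and was also run on the 14834 genes that edgeR tested. For the similarity of comparisons, 100 draws of unchanged groups were simulated without the replicate letter, and 100 with letter means and the dispersion of the block fit. The gene test was tested on simulated data for R820W vs WT with 14834 genes and 10 draws of 200 changed genes. It recovered 12.1% of genes changed 2-fold and 62.9% of those changed 4-fold, with 76 false calls over the 10 draws. These draws left out the difference between the replicate letters, so the rates in the data may differ. The list test called a simulated list of 30 genes changed 1.5-fold in 10 of 10 draws and called 0 of 780 other list tests, in simulated genes that were independent of one another. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.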

Results

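The series asked which pathways differ between keratinocytes that express hypomorphic CARD14 variants and those that express WT CARD14. CARD14 is a scaffold protein of epithelial cells that signals to NF-kB through BCL10 and MALT1. CARD14-knockout HaCaT cells received WT CARD14 or the variant R820W, N737H or I593T from a plasmid that also encodes GFP. RNA of GFP-positive cells was counted in 2 libraries per group, A and B, with 17892608 to 24629860 counts each. Most markers of other cell types were near 0. The fibroblast marker VIM had a mean CPM (counts scaled to library size) of 0.235 and the leukocyte marker PTPRC 0.0646. The markers in the same lists with a mean above 1 CPM, named after their values were seen, were FN1 (282), CD68 (63.6), CDH2 (21.7), MITF (8.51), CD74 (3.89), PMEL (1.32) and MLANA (1.18).

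CARD14 RNA was present in every library, at levels that varied within the variant groups. It stood at 1127 and 978 CPM in the WT libraries A and B, and at 1190 and 1410 with R820W. With N737H it was 444 in A and 1005 in B, and with I593T 500 in A and 1394 in B. No variant differed from WT by more than this spread. The log2 fold changes were 0.30 ± 0.49 (SE, n = 2 per group) for R820W, -0.54 ± 0.49 for N737H and -0.15 ± 0.49 for I593T (edgeR adjusted p = 1.00 in each). The I593T value was 0.40 without its A library. The counts cannot tell which construct a transcript came from, and no library without plasmid was analysed here.

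MYC, the transcription factor in the series title, was expressed at 743 ± 1.94 CPM (SD, n = 2) with WT CARD14. It was at 746 ± 61.0 with R820W, 690 ± 69.8 with N737H and 779 ± 53.2 with I593T. Its log2 fold changes against WT were 0.01, -0.11 and 0.07, each with an SE of 0.15. Their 95% intervals were -0.35 to 0.36, -0.46 to 0.25 and -0.28 to 0.42. No change of MYC RNA was detectable within those limits.

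**Figure D1:**
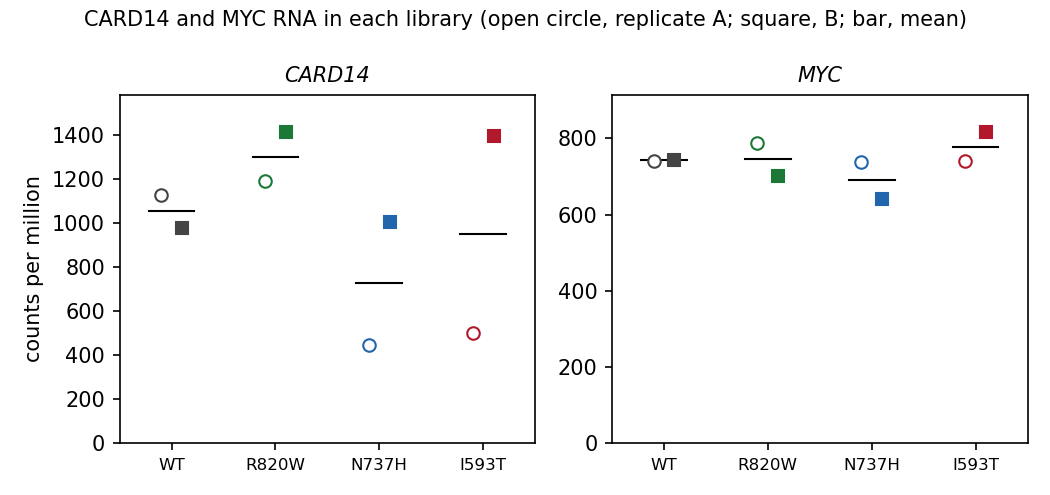
CARD14 and MYC RNA in CPM (vertical axes, from 0) for WT and the 3 variants, with an open circle for replicate A, a square for replicate B and a bar for the mean of both. CARD14 was at 444 and 500 CPM in the A libraries of N737H and I593T and at 978 or more in the other 6, while MYC lay between 641 and 816 in all 8.

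With R820W, no gene passed the test against WT. The genes of smallest p that were higher in both replicates included FOSB, a subunit of the AP-1 transcription factor, at 23.6 against 11.1 CPM (log2 fold change 1.08 ± 0.24 SE). ATF3, a stress-induced transcription factor, had a log2 fold change of 1.20 ± 0.35, which was 0.75 without WT replicate A and 1.95 without WT replicate B. CCL4, a chemokine, had 1.29 ± 0.38, with 19.7 and 9.45 CPM in A and B against 5.59 and 6.37 in WT, and was at 0.67 without R820W replicate A. AK097957 (1.43 ± 0.33) and LOC23117 (0.70 ± 0.21) completed the 5 higher genes. The 5 lower ones were E10222 (-1.09 ± 0.33), TSPYL1 (-0.43 ± 0.14), NUDT19 (-0.48 ± 0.16), TMA16 (-0.45 ± 0.15) and PSMC3IP (-0.43 ± 0.14). None of these 10 genes passed (edgeR adjusted p = 1.00 for each). In this and every other comparison of groups, fewer genes had an unadjusted p under 0.05 than chance would give. The p-values of the main fit thus ran high, and a lack of calls does not show a lack of change. Unadjusted p-values under 0.05 were found for 154 genes, where 742 of 14834 would come by chance. That count was 384 with the replicate block and ran from 60 to 921 with each library left out. DESeq2 and limma voom also called 0 genes, and DESeq2 with the replicate block called 1 (CCL4L2, named after its value was seen).

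Interferon-stimulated genes rose as a list with R820W, with 33 of 38 members higher (camera adjusted p = 1.5e-06, and adjusted p = 0.707 with an estimated correlation). IFIT3 and ISG15, its most abundant members, had log2 fold changes of 0.02 ± 0.37 and -0.08 ± 0.41. The list's median difference from WT was 0.43 in replicate A and 0.02 in B, and without WT replicate A the call was lost and camera's direction turned (median 0.0045, adjusted p = 0.417). Cytosolic ribosomal protein genes fell as a list, with 66 of 70 lower (adjusted p = 0.00014, and 0.888 with an estimated correlation). Their median was 0.19 in A and -0.39 in B, and without WT replicate B they rose (median 0.17, adjusted p = 8.8e-05). Nuclear respiratory-chain genes behaved in the same way, with 27 of 31 lower (adjusted p = 0.018, and 0.940 with an estimated correlation) and a median of 0.19 without WT replicate B. Their call was also lost without R820W replicate A (adjusted p = 0.409). MYC and its ribosome-biogenesis targets fell, with 31 of 39 lower and a median of -0.07 (adjusted p = 0.00031, and 0.707 with an estimated correlation). NPM1, a nucleolar protein, was at -0.26 ± 0.17 and HSPD1 at -0.12 ± 0.19. This call was lost without WT replicate A (adjusted p = 0.170) or R820W replicate B (0.104). Heat-shock genes fell, with 15 of 16 lower (adjusted p = 0.035, and 0.801 with an estimated correlation), and that call was lost without R820W replicate B (0.977). Without WT replicate A the direction turned (median 0.17, adjusted p = 0.164). Adjusted over the list alone, 0 members of each of the 26 lists passed. The 5 list calls became 8 without WT replicate B or R820W replicate A, and fry called 0 lists for each variant.

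With N737H, the lower genes of smallest p included genes of epidermal differentiation and inflammation, though none passed the edgeR test. The naming rule required them to be lower in both replicates, so that is no added support. Over all genes, 39.3% had the same direction in A and B. CSF3, a granulocyte growth factor, was at 8.32 against 20.2 CPM in WT (log2 fold change -1.28 ± 0.24 SE). CDKN1A, the cell-cycle inhibitor p21, was at 195 against 357 (-0.87 ± 0.17). SPRR1B, a cornified-envelope precursor, was at 9.87 against 25.8 (-1.39 ± 0.27), and the chemokine CCL20 at 5.27 against 11.5 (-1.13 ± 0.25). The 5 higher genes were AL832891 (2.32 ± 0.48), AK097957 (1.41 ± 0.33), ITGBL1 (0.77 ± 0.20), LINC00338 (0.77 ± 0.25) and CYR61, a matricellular growth-factor gene (1.20 ± 0.41). Without N737H replicate B, AL832891 was at 1.64 and CYR61 at 0.77. The edgeR adjusted p was 1.00 for each of these 9 genes, and 362 genes had an unadjusted p under 0.05 against 742 by chance. That count was 670 with the replicate block, 127 without N737H replicate B and 1436 without N737H replicate A. DESeq2 and limma voom called 0 genes. With the replicate block edgeR called 0, and DESeq2, which was given all 22949 genes with a count, called 20, of which 17 were lower. Given only the genes that edgeR tested, DESeq2 called 1 higher gene, AL832891, and with the block 23 genes, 21 of them lower. The 17 included CSF3, CDKN1A, SPRR1B and CCL20. Among them, named after their values were seen and with values of that DESeq2 fit, were CEACAM6 (-1.54 ± 0.24), IL36G (-1.20 ± 0.22) and PLAU (-0.71 ± 0.15).

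**Figure D2:**
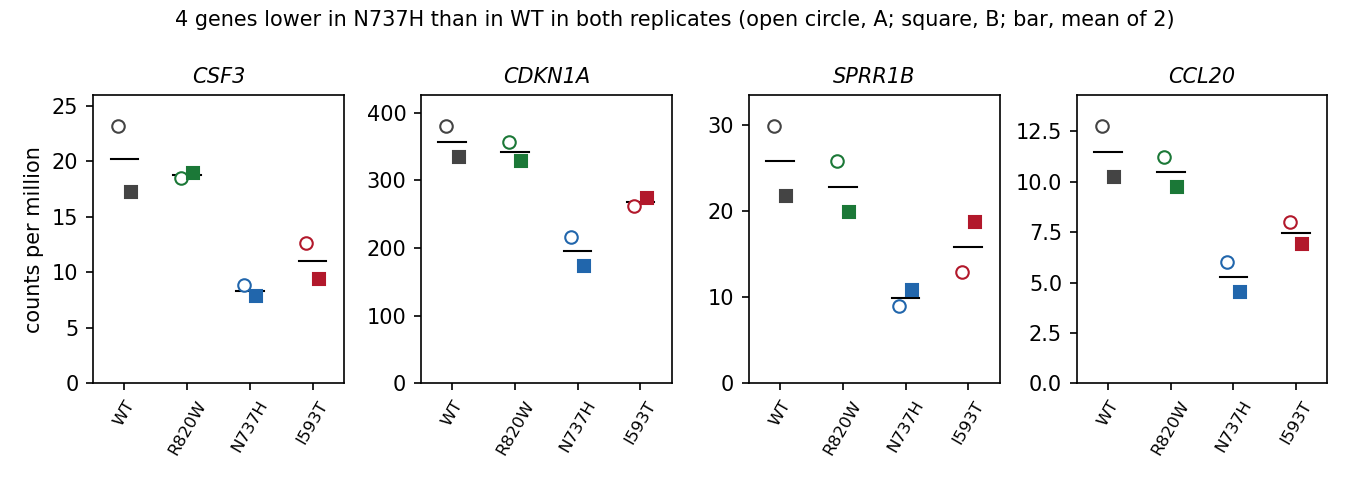
CPM (vertical axes, from 0) of CSF3, CDKN1A, SPRR1B and CCL20 in WT and the 3 variants, with an open circle for replicate A, a square for replicate B and a bar for the mean of both. Both N737H libraries lie below both WT libraries for each gene, for example at 8.32 against 20.2 on average for CSF3, and no gene passed the edgeR test. The genes were chosen to be lower in both replicates.

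By camera with the preset correlation, 11 lists fell with N737H and 0 rose, and 6 were called without N737H replicate B and 17 without WT replicate B. NF-kB target genes had 21 of 31 members lower and a median of -0.33 (adjusted p = 3.7e-05, and 0.707 with an estimated correlation). The median was -0.31 in A and -0.40 in B. SDC4 and CXCL1, the most abundant members, were at -0.33 ± 0.27 and -0.46 ± 0.43. NFKBIA, the inhibitor of NF-kB and named after its values were seen, was not lower overall (0.44 ± 0.54), with 83.1 against 117 CPM in A and 184 against 79.3 in B. Adjusted over the list alone, 2 members passed, CSF3 and CCL20. Cornified-envelope and late differentiation genes had 18 of 24 lower (median -0.61, adjusted p = 0.0015, and 0.504 with an estimated correlation). This list was weakly expressed: the median level of its 33 genes was 1.01 CPM of the raw counts, and 24 passed the filter. Adjusted over the list alone 2 passed, SPRR1B and SPRR1A. Antimicrobial and alarmin genes had 12 of 14 lower (adjusted p = 0.00036, and 0.504 with an estimated correlation), with medians of -0.0033 in A and -0.99 in B. Basal keratinocyte and hemidesmosome genes had 17 of 19 lower (adjusted p = 6.7e-06, and 0.504 with an estimated correlation), among them the laminin chain LAMA3 (-0.81 ± 0.51). Cell-junction genes had 21 of 24 lower (adjusted p = 5.9e-05, and 0.504 with an estimated correlation), with the desmosomal DSP at -0.37 ± 0.15. CARD14 signalling partners had 19 of 22 lower (adjusted p = 0.0082, and 0.504 with an estimated correlation), with BCL10 at -0.41 ± 0.15. Stress keratins had 4 of 5 lower (adjusted p = 0.014, and 0.707 with an estimated correlation), with KRT17 at -0.54 ± 0.19. NRF2 target genes had 17 of 22 lower (adjusted p = 0.0040, and 0.707 with an estimated correlation), with FTH1 at -0.49 ± 0.18. Glycolysis and hypoxia genes had 28 of 29 lower (adjusted p = 0.00083, and 0.707 with an estimated correlation), with medians of 0.07 in A and -0.44 in B. Integrated stress response genes (22 of 27 lower, adjusted p = 0.035) and MYC and its ribosome-biogenesis targets (31 of 39, adjusted p = 0.028) had 0.781 and 0.801 with an estimated correlation.

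Of the 11 calls, the cell-junction call alone held with each library left out. Without WT replicate A the calls ended for NF-kB targets (median 0.16, adjusted p = 0.113), basal genes (0.0798), CARD14 partners (0.193), MYC targets (0.670) and integrated stress response genes (median 0.07, 0.523). Without N737H replicate B, the library with the most genes detected (21059), they ended for NF-kB targets (median -0.07, 0.417), antimicrobial genes (0.162), stress keratins (0.174), NRF2 targets (median 0.01, 0.413), glycolysis genes (0.0549), MYC targets (median 0.01, 0.869) and integrated stress response genes (0.990). Without WT replicate B they ended for antimicrobial genes (median 0.12, 0.0909), stress keratins (0.183) and glycolysis genes (0.869), and without N737H replicate A for cornified-envelope genes (0.106). Of the lists with no call, those with more members lower were epidermal barrier lipid genes (16 of 21), sterol biosynthesis genes (18 of 24), immediate-early and AP-1 genes (18 of 27), endoplasmic-reticulum chaperones (15 of 20), heat-shock genes (12 of 16), p53 targets (14 of 20), aryl hydrocarbon receptor targets (6 of 8), respiratory-chain genes (26 of 31), ribosomal protein genes (49 of 70) and type 2 and atopy-related genes (7 of 8). Adjusted over the list alone, 1 p53 target passed, CDKN1A. Proliferation genes were higher for 20 of 34 and interferon-stimulated genes for 23 of 38. Several of these lists had opposite medians in A and B. They were respiratory-chain (0.29 and -0.44), ribosomal protein (0.33 and -0.38), type 2 and atopy-related (0.22 and -0.60), sterol biosynthesis (0.11 and -0.21), heat-shock (-0.11 and 0.05), proliferation (0.37 and -0.26) and interferon-stimulated genes (0.43 and -0.20). Of the 3 tested members of each list of other cell types, 2 melanocyte, 0 immune-cell and 3 kidney-derived or endothelial markers were higher, with immune-cell medians of 0.45 in A and -1.98 in B. The fibroblast list had 1 tested member, FN1.

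With I593T, CYR61 was higher than in WT in both replicates, as the naming rule required. It was at 110 and 260 CPM in A and B against 57.1 and 45.5 (log2 fold change 1.85 ± 0.41 SE, and 1.09 without I593T replicate B). ANKRD1, which like CYR61 is a target of the co-activator YAP, was at 12.1 against 4.28 (1.499 ± 0.42). AL832891 (2.04 ± 0.48, and 2.70 without WT replicate A), KDM2A (0.61 ± 0.18) and SENP3 were the other 3 higher genes. SENP3 rested on 1 library, with 1192 CPM in B and 1.41 in A. The 5 lower genes were YPEL5 (-0.62 ± 0.16), AKR1C1 (-1.02 ± 0.27), CSF3 (-0.87 ± 0.24), SPRR1A (-1.34 ± 0.38) and PTAFR (-0.74 ± 0.21). None of these 10 genes passed (edgeR adjusted p = 1.00 for each), and 212 genes had an unadjusted p under 0.05 (500 with the replicate block, and 90 to 804 with each library left out). DESeq2 called 3 genes, CYR61, SENP3 and CTLA4, or the first 2 when given only the genes that edgeR tested. CTLA4 also rested on replicate B alone, and limma voom called 0. Without I593T replicate A edgeR called 3 genes, SENP3, CTLA4 and PTP4A2, and without WT replicate B 1, TMED9. With the replicate block DESeq2 called 2, CYR61 and SERPINB13, and edgeR 0. CTLA4, PTP4A2, TMED9 and SERPINB13 were named after their values were seen.

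By camera 4 lists fell with I593T and 0 rose, with 2 calls without N737H replicate B, 9 without I593T replicate B, 8 without WT replicate B and 12 without WT replicate A. They were cell-junction genes (19 of 24 lower, adjusted p = 0.0058), cornified-envelope and late differentiation genes (19 of 24, 0.014), antimicrobial and alarmin genes (12 of 14, 0.038) and basal keratinocyte and hemidesmosome genes (17 of 19, 0.042). With an estimated correlation their adjusted p was 0.504, 0.504, 0.707 and 0.707. Adjusted over the list alone, 0 members passed in each. MYC and its ribosome-biogenesis targets, which fell as a list with R820W and N737H, had no call with I593T. Of these, 23 of 39 were higher (median 0.015, camera adjusted p = 0.394). Among the lists called, DSP was at -0.28 ± 0.15, and KLK5, an epidermal protease, at -0.25 ± 0.34. KLK5 belongs to the cornified-envelope list, whose genes had a median level of 1.01 CPM. The antimicrobial list had opposite directions in the replicates, with a median of 0.10 and 8 of 14 higher in A, and -0.56 and 12 of 14 lower in B. The basal list had a median of -0.33 in A and 0.09 in B. Its call ended without WT replicate A (median 0.22, adjusted p = 0.714), I593T replicate A (0.309) or N737H replicate B (0.0597). The cell-junction call ended without WT replicate A (median 0.03, 0.244) or I593T replicate A (0.178), and the cornified-envelope call without WT replicate B (median 0.03, 0.261) or I593T replicate A (0.373). The antimicrobial call ended without WT replicate B (0.622), I593T replicate B (0.482) or N737H replicate B (0.0589).

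**Figure D3:**
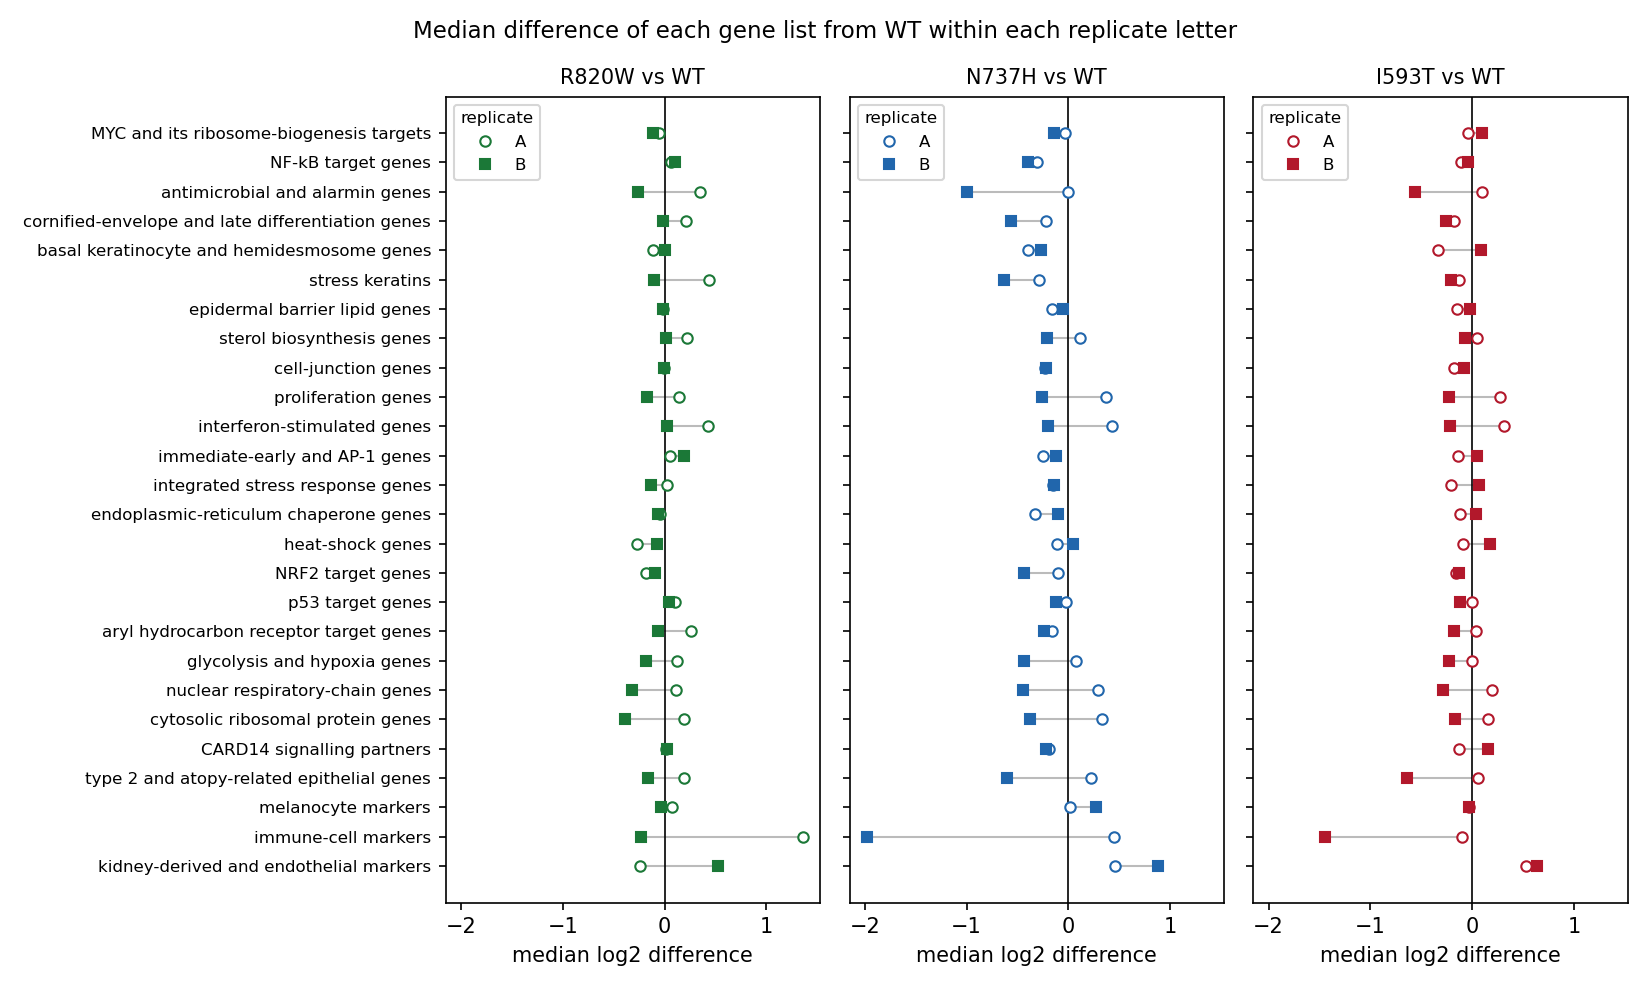
Median log2 difference from WT (horizontal axis) of the members of each of the 26 tested gene lists (vertical axis), for R820W, N737H and I593T, with an open circle for replicate A and a square for replicate B joined by a line. For NF-kB target genes with N737H the medians are -0.31 and -0.40, while for ribosomal protein genes with R820W they lie on opposite sides of 0, at 0.19 and -0.39.

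For the mean of the 3 variants against WT, no gene passed. CYR61 was higher (log2 fold change 1.34 ± 0.36 SE), and its level with each variant exceeded WT in both replicates, with means of 100, 118 and 185 CPM for R820W, N737H and I593T against 51.3. AK097957 (1.25 ± 0.28) and AL832891 (1.79 ± 0.42, and 2.45 without WT replicate A) were the other 2 higher genes, and CSF3 (-0.75 ± 0.18), YPEL5 (-0.51 ± 0.13) and PTPRE (-0.72 ± 0.19) the 3 lower ones. The edgeR adjusted p was 1.00 for each, with 195 genes at an unadjusted p under 0.05 (527 with the replicate block, and 111 to 1024 with each library left out). DESeq2 and limma voom called 0 genes, edgeR 1 (TMED9) without WT replicate B, and DESeq2 with the replicate block 3, CYR61, CEACAM6 and UBE2F-SCLY (at 0 in both WT libraries), of which the last 2, and TMED9, were named after their values were seen.

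Between variants, the chemokines CCL4 and CCL4L2 were higher with R820W. CCL4 was at 14.6 CPM with R820W, 2.24 with N737H and 4.11 with I593T. Its log2 fold change was 2.70 ± 0.41 SE against N737H and 1.83 ± 0.39 against I593T, or 2.06 and 1.19 without R820W replicate A. CCL4L2, a near-identical copy of CCL4 with which it can share reads, was at 2.67 ± 0.69 against I593T and 1.58 without R820W replicate A. KRT15, a keratin of basal keratinocytes, was at 128 with R820W and 62.5 with I593T (1.04 ± 0.26). The receptor kinase AXL was lower with R820W than with N737H (-0.57 ± 0.19) and I593T (-0.66 ± 0.19), as was RGS7 (-0.83 ± 0.25 and -0.88 ± 0.25). AL832891 was at -1.32 ± 0.46 for R820W against N737H, and at -0.65 without N737H replicate B. The read-through model SLMO2-ATP5E, which can share reads with its 2 parent genes, was higher with R820W than with N737H (4.15 ± 0.83, and 2.41 without R820W replicate A) and lower with N737H than with I593T (-2.74 ± 0.80). For N737H vs I593T, ZNF160 (0.61 ± 0.22), RGPD6 (0.48 ± 0.18) and ZNF799 (0.64 ± 0.25) were the higher genes. SENP3 stood apart in I593T replicate B alone, and without I593T replicate A edgeR called SENP3, CTLA4 and PTP4A2 in each comparison of another variant with I593T. No gene passed the edgeR test in the 3 comparisons (adjusted p = 1.00 for each named gene), and 242, 182 and 169 genes had an unadjusted p under 0.05. With the replicate block these counts were 527, 385 and 313, and with each library left out they ran from 92 to 877, 71 to 688 and 70 to 1076. With the replicate block edgeR called 1 gene, CCL4L2, higher with R820W than with N737H (2.82 ± 0.21, adjusted p = 0.035). DESeq2 called 3, 0 and 1 genes, and 28, 4 and 2 with the block, and limma voom 0. CTLA4, which had 1 count in all over the R820W and N737H libraries, was 1 of the 3 and also the call for N737H vs I593T, where it was 1 of 2 with the block. On the genes that edgeR tested, DESeq2 called 3 (with CCL4L2 in place of CTLA4), 0 and 0, and 30, 7 and 1 with the block.

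The 3 comparisons with WT share the WT libraries, which alone make their fold changes correlate. Across 14834 genes, which are not independent replicates, the log2 fold changes of R820W and N737H had a Pearson correlation of 0.57 and a Spearman correlation of 0.52. For R820W and I593T both were 0.46, and for N737H and I593T they were 0.46 and 0.53. Simulated unchanged groups gave a Pearson correlation of 0.50 (SD 0.01 over 100 draws) and a Spearman correlation of 0.46 in each pair. The direction was the same for 71.1%, 69.8% and 73.0% of genes, against 66.6% to 66.7% in the simulation (SD 0.4% in each pair). The observed covariances were 0.142, 0.101 and 0.123, against a simulated 0.144 in each pair. That simulation leaves out the difference between the replicate letters, which cancels between groups and raises its covariance. A simulation that keeps it, added after the data were seen, gave a covariance of 0.101 to 0.102 (SD 0.005 or less), below the observed value for R820W with N737H and for N737H with I593T. On the 8073 genes with a mean of at least 10 CPM it gave 0.027 to 0.028 and the first simulation 0.047, against an observed 0.020 for R820W with N737H and 0.040 for N737H with I593T. The correlation of N737H with I593T on these genes was 0.629, against 0.50 in both simulations (SD 0.01 and 0.02). Over all genes the correlations and same-direction shares of both simulations agreed to 0.01 and 0.1%. The same-direction shares and the correlation of 0.629 exceeded both simulations. So did, over all genes, the Pearson correlation of 0.57 for R820W with N737H and the Spearman correlations of 0.52 and 0.53. On the genes with at least 10 CPM the Pearson correlation of R820W with N737H was 0.469, below both simulations. Over all genes, the Pearson correlations of 0.46 for I593T with R820W and with N737H also lay below both. Whether any covariance exceeds its simulated value rests on the simulation. Both simulations drew each gene independently of the others, so their SDs leave out genes that move together in a library. For this reason, and because the WT libraries are too few to be split, no excess is read as a shared effect. With no calls, the lists of called genes shared 0 genes where independent lists would share 0. Comparisons that share no library, 1 variant in A and another in B, had correlations from -0.20 to -0.09. The differences of 1 variant from WT in A and in B had Pearson correlations of -0.02 for R820W, -0.23 for N737H and -0.09 for I593T. Within each comparison, the direction was the same in A and B for 47.5%, 39.3% and 47.3% of genes.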

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

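The tests in this part were chosen after the results were seen. CCL4L2 differed between R820W and N737H in the fit with the replicate letter as a block (log2 fold change 2.82 ± 0.21 SE, edgeR adjusted p = 0.0349), at 69.6 and 21.5 CPM in the R820W libraries against 8.34 and 3.69 with N737H. It shares sequence with CCL4, which was at 2.67 ± 0.34 in the same fit (adjusted p = 0.410). CCL4 was called in this comparison by DESeq2 (adjusted p = 1.2e-05, and 2.7e-07 with the block) and by edgeR with no filter on low counts (0.00025). The main edgeR fit and limma voom did not call it.

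Several lists had medians above WT in both replicates of 1 variant and below WT in both replicates of another. For these the mean of the medians differed by 0.44 for NF-kB target genes, 0.31 for immediate-early and AP-1 genes, 0.22 for CARD14 signalling partners and 0.15 for p53 targets between R820W and N737H. Between R820W and I593T it differed by 0.16 for NF-kB targets and 0.14 for p53 targets, and between N737H and I593T by 0.17 for melanocyte markers. The opposite directions themselves were not tested. All 26 tested lists were scanned in each pair of variants. How many would show such opposite directions by chance was not worked out, so their number is not read as a difference between variants. For CARD14 signalling partners the R820W medians were close to WT, at 0.012 in A and 0.023 in B. The fit of both replicates gave a median of -0.030, with 12 of 22 members lower. NF-kB targets with R820W were also close to WT, at 0.064 in A and 0.101 in B. Their fitted median was 0.025, with 16 of 31 members higher and no call (camera adjusted p = 0.194 with the preset correlation). Camera on the direct differences called 13, 11 and 9 of 26 lists for R820W vs N737H, R820W vs I593T and N737H vs I593T with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.218).

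Beside the doubted N737H library of replicate B, 3 sources of the low NF-kB targets of N737H were considered. A high level in the WT libraries alone is only partly argued against, since the list was also lower than with R820W in both replicates, where the median nearer 0 was -0.34. Without WT replicate A the median against WT was 0.16, which cannot decide this. That fit sets both N737H libraries against a B library alone, and the list was lower in B than in A (median -0.38). Less CARD14 RNA remains open. The median was still -0.40 in replicate B, where CARD14 RNA was at 1005 CPM against 978 in WT, but this is 1 pair of libraries. Its N737H library is the doubted one, with the most genes detected (21059). Without it, the median of the remaining A library against both WT libraries was -0.07, while within A it was -0.31. Correlated genes moving together in a few libraries also remain open, with an adjusted p of 0.707 with an estimated correlation. An effect of the variant itself cannot be told apart from these by 2 libraries per group.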

How the results depend on the processing

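The replicate block with an estimated correlation, and the fits without both the N737H and I593T libraries of replicate B, were added after the data were seen, as were DESeq2 on the genes edgeR tested and a simulation with the replicate letters. Of the 912 alternative values for 57 named gene results, 904 kept their direction, and 34 values passed the threshold. Apart from MYC, these genes were named only if A and B had the same direction, so that share was largely set by the rule. Of the 8 values that reversed, 7 were for MYC. The counts of 0 genes stayed at 0 with RLE, limma voom, the stricter filter, a fit of only the groups compared (not run for the mean of variants), and CARD14 and the mitochondrial gene left out. With no filter on low counts they were 2 for R820W, 2 for N737H, 8 for I593T, 2 for the mean of variants, and 8, 10 and 11 for R820W vs N737H, R820W vs I593T and N737H vs I593T. DESeq2 called 3 for I593T, 3 for R820W vs N737H and 1 for N737H vs I593T. The replicate block called 1 for R820W vs N737H, and in DESeq2 1, 20 and 2 for R820W, N737H and I593T, 3 for their mean, and 28, 4 and 2 for the pairs. On the genes edgeR tested, DESeq2 called 1 for N737H, 2 for I593T and 3 for R820W vs N737H, and with the block 1, 23 and 2 for the variants, 4 for their mean, and 30, 7 and 1 for the pairs. With each library left out the counts ran from 0 to 3 for I593T, R820W vs I593T and N737H vs I593T, where the 3 calls came without I593T replicate A, and from 0 to 1 for the mean of variants. They stayed at 0 for R820W, N737H and R820W vs N737H. The lone library left in a group was assumed to vary like the other groups. The cause was not tested.

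With an estimated correlation, with or without the replicate block, 0 lists were called for each variant. With the block and the preset correlation, 7, 15 and 6 were called. The added calls were endoplasmic-reticulum chaperones (adjusted p = 0.019) and NRF2 targets (0.024) with R820W. With N737H they were AP-1 genes (0.043), chaperones (0.011), immune-cell markers (0.038) and kidney-derived or endothelial markers (0.019). With I593T they were glycolysis genes (0.038) and kidney-derived or endothelial markers (0.032). The block changed no other call. With each library left out, list counts ran from 5 to 8 for R820W, 6 to 17 for N737H and 2 to 12 for I593T, and without both doubted libraries I593T had 10. CARD14 ran from -1.08 to 0.40 for I593T, reversed without its A library.

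MYC reversed near 0. With R820W it was -0.0069 without a filter, -0.00013 in DESeq2 and -0.0020 with the block in DESeq2. With each library left out it ran from -0.075 to 0.103, with -0.016 without N737H replicate B. It ran from -0.232 to 0.013 with N737H and from -0.0046 to 0.135 with I593T. SENP3 ran from -9.54 to 0.19 for R820W vs I593T, reversed without I593T replicate B. Medians of lists that reversed with a library left out had these ranges. With R820W they were 0.0045 to 0.54 for interferon-stimulated genes (whose camera direction turned), -0.47 to 0.17 for heat-shock, -0.35 to 0.19 for respiratory-chain and -0.36 to 0.17 for ribosomal protein genes. With N737H they were -0.18 to 0.011 for MYC targets, -0.76 to 0.16 for NF-kB targets, -1.17 to 0.12 for antimicrobial genes, -0.33 to 0.070 for integrated stress response genes and -0.36 to 0.014 for NRF2 targets. With I593T they were -0.50 to 0.029 for cornified-envelope, -0.29 to 0.22 for basal and -0.19 to 0.028 for cell-junction genes. The correlation of comparisons at 10 or more CPM was 0.469 for R820W with N737H, 0.459 for R820W with I593T and 0.629 for N737H with I593T, where unchanged groups gave 0.50 in each pair in both simulations.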

Other observations

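The tests in this part were chosen after the results were seen, except the count of other splits of the libraries, and the genes were named after their values were seen. In the edgeR fit with group and replicate letter, 254 genes were higher and 226 lower in B than in A. Between groups the same fit called at most 1. The letters set 4 libraries against 4 and a pair of groups 2 against 2, so these counts do not compare sizes of effect. Each letter was read as 1 experiment, so a difference between experiments was not replicated. Sterol biosynthesis genes were higher in B for 24 of 24 members, 9 of them past the threshold (camera adjusted p = 2.6e-13, and 0.383 with an estimated correlation). CYP51A1, an enzyme of that pathway, averaged 513 CPM in B against 288 in A (log2 difference 0.83 ± 0.08 SE, adjusted p = 0.0070). NF-kB target genes were lower in B, with 9 of 31 past the threshold (median -0.38, camera adjusted p = 1.6e-08, and 0.383 with an estimated correlation). Among them, the cytokine IL6 averaged 6.24 against 17.0 and the signalling adaptor TRAF1 6.61 against 20.3 CPM. Heat-shock genes had 7 of 16 past the threshold, all lower (camera adjusted p = 5.0e-07, and 0.470 with an estimated correlation). TXNIP, a regulator of glucose uptake, averaged 10.0 against 56.6, and CEACAM5 29.1 against 3.62. The real split gave 480 genes and the highest of the other splits that take 1 library of each group gave 0, but 8 such splits are too few for a share under 0.05, and 1 split reached that count, the real one.

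The I593T library of replicate B held 14874 counts of CTLA4, an inhibitory receptor of T cells, where the other 7 libraries held 0 or 1, as well as 1192 CPM of SENP3 against at most 1.96 elsewhere, and 906 of PTP4A2 against at most 89.4. A first test for T cells, the sum of 16 markers, decided nothing, since it was 115 CPM in this library and 110 to 172 in the others, where IL7R alone gave 108 to 171. A second test, added after that outcome, took the 14 markers under 1 CPM in each other library, and their sum of 1.29 against 736 for CTLA4 argued against T cells in the sorted sample. Reads moved from the overlapping model SENP3-EIF4A1 are also argued against, since both together reached 4450 CPM against at most 3724 elsewhere. So is the I593T construct at the level of its A library, which had a CTLA4 count of 0. CARD14 RNA was at 500 CPM in that library against 1394 in B, so this library cannot speak for the higher level. Plasmid or amplified DNA of single genes is a candidate source that was not tested.

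The N737H library of replicate B detected 21059 genes. Library size is argued against, since 20973 remained after thinning to the smallest library, where the highest of the others was 18855. The N737H construct at the level of its A library is argued against as well, since that library detected 17836. CARD14 RNA was at 444 CPM there against 1005 in B, so an effect at the higher level stays open. Counts spread over gene models that are otherwise silent were in keeping with the data: olfactory receptor models held 44.7 CPM of the raw counts in this library and at most 21.96 in the others. Here 135 of these models had a count, against at most 81 elsewhere. They are themselves among the genes detected, so this describes the pattern and is no separate test of it. Whether such counts come from genomic DNA or from unspliced RNA stays open.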
